A study of Homo sapiens with 7 samples.

How the data were processed

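Total RNA from 7 cultures of cells labelled MCF-7, a breast cancer cell line, had been labelled with biotin and hybridised to Affymetrix PrimeView arrays, from 100 ng of RNA per sample, per the labels' protocols. Of the 7 arrays, 3 carried RNA from cells given graphene oxide, 3 from cells given graphene nitrite and 1 from control cells. Both treatments were given at the concentration that inhibits by 25%, per the series' design text. The concentrations themselves and the exposure times are not given in the sources used here. The control array is numbered 1 in its title and 3 in its source name.

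The deposited values are log2 signals, 1 per probe set and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. The version, the background correction and the normalization method are not given in the sources used here. The 6 treated arrays of the deposited log2 table share nearly the same distribution, with medians from 3.41 to 3.48, while the control array has a median of 5.30 and a wider spread. The deposited control values are therefore not on the scale of the treated values. What made the difference stays unknown. For arrays, their number limits the precision.

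The table holds 49395 probe sets. The platform annotation gave 1 gene symbol for 44994 of them, several for 1832 and none for 2569. Symbols were looked up by Entrez ID in a RefSeq gene table (GRCh38.p14), where 44967 of the probe sets with 1 symbol had a match and 0 symbols needed an update. Each of the resulting 18132 genes was represented by its probe set with the highest mean over all arrays. Genes in the lowest 40% by mean over all arrays were left out, which left 10879 genes for the tests. Probe sets with several symbols were not used for any gene, and genes on the Y chromosome and XIST were not named.

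All 7 arrays entered 1 linear model per gene, fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with a mean for each of the 3 groups and no replicate block. All limma tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The fit had 4 residual and 4.19 prior degrees of freedom. The spread came from the 6 treated arrays alone, since the control has 1 array, which was assumed to vary like them. The labels call the samples biological replicates, so p-values measure the spread between such cultures of the treatments, and nothing measures that of the control. No comparison with the control had a replicate check on the control side. Confidence intervals are 95% intervals from the same fit. A pseudocount was not needed because the values were on the log2 scale, so the alternative planned for it was not run.

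Because the control array lay on another scale, each comparison was also computed after quantile normalization of the 7 arrays and after centring each array on its median. The median change of all genes for graphene oxide against control was -2.09 as deposited, -0.26 after median centring and 0.12 after quantile normalization, on the log2 scale. For graphene nitrite against control it was -2.06, -0.20 and 0.12. A gene was counted as past the threshold in all 3 scalings where it passed in the same direction as deposited, centred and quantile-normalized. This count was chosen after the data were seen. Because the deposited control lies higher, the count admits few rises, so it does not weigh rises against falls.

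Before the data were examined, 32 gene lists were fixed: 28 pathways or gene groups and 4 sets of marker genes of other cell types. The 31 lists with at least 3 genes tested were tested with limma's camera, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares the moderated t-statistics (change over error) of a list with those of all other genes, while fry tests a list's own change. An offset shared by all genes moves these statistics most where the error is small, so camera calls as deposited depend on the control's scale. P-values were adjusted over the lists of a comparison. The design, the tests, the filter, the rule for named genes and the alternatives were also fixed before the data were examined, except the alternatives given as chosen later.

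The text names, for each comparison, genes among the 12 largest rises and 12 largest falls past the threshold whose arrays do not overlap. Where fewer than 3 genes passed in a direction, the 5 of lowest p are given as not past the threshold. From each list described in detail, up to 4 members of lowest adjusted p are named. Of the other cell type lists, the 3 members with the highest mean are named. Genes of luminal, epithelial and other identity were chosen after their values were seen. Levels are given as mean ± SD over arrays of log2 signals, and percentiles are ranks of a gene among the 18132 genes of an array.

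The steps were tested on simulated data with known changes. For graphene oxide against control the fit recovered 71% of genes simulated with a 2-fold change and 100% of those with a 4-fold change, with 14 false calls among 10879 genes. For graphene nitrite against control the shares were 75% and 100%, with 13 false calls. With so few false calls, the simulated control did not carry the scale difference of the real one. The rates against control therefore do not hold for the deposited control array. For graphene nitrite against graphene oxide they were 95% and 100%, with 15 false calls. Camera found a list shifted by 0.5 on the log2 scale and 0 other lists.

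The alternatives tried were no gene filter and a stricter one (60% left out), the mean over a gene's probe sets, each probe set alone, both scalings, eBayes without a trend, robust eBayes, array weights, an adjusted p of 0.10, a minimum of a 1.5-fold difference, the replicate number as a block, fits restricted to the groups compared, and leaving out each treated array in turn. Alternatives added after the data were seen combined quantile normalization with a 1.5-fold minimum, with a batch term for the arrays numbered 3, or without graphene oxide replicate 3. A further one added that batch term to the comparison of the treatments. RNA quality was described with the 12 poly-A spike and 9 hybridization spike probe sets, 23 background probe sets and the 3' and 5' probe sets of ACTB, GAPDH and 18S rRNA. Where a control signal lay below the background mean of the control array, a rise is counted from that mean, as a lower bound. That mean runs over background probe sets of GC counts 3 to 25, whose signals rose with the GC count from 5 on. At GC counts of 5, 14 and 25 they were at 2.14, 2.61 and 9.31 on the control array and at 1.69, 1.99 and 7.88 on the treated arrays. The mean was not matched to the probes of a gene, so a signal below it can still exceed their own background. The shared control was handled by simulating unchanged groups against 1 common control, 100 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.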

Results

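Gene expression was measured in cells labelled MCF-7 after exposure to graphene oxide (3 arrays) or graphene nitrite (3 arrays), with 1 array of control cells. Graphene oxide is a sheet of carbon that carries oxygen groups, studied as a carrier for drugs and imaging agents. What distinguishes graphene nitrite is not described in the labels. The design asked how each material changes expression at the concentration that inhibits by 25%, with candidate markers for imaging and therapy in view. The 6 treated arrays correlated with each other at r = 0.981 to 0.995 across probe sets, and with the control array at 0.870 to 0.895. Median signals were 3.41 to 3.48 (log2) on the treated arrays and 5.30 on the control array. Background probe sets, which match no transcript, averaged 2.86 to 2.98 on the treated arrays and 3.78 on the control array.

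**Figure D1:**
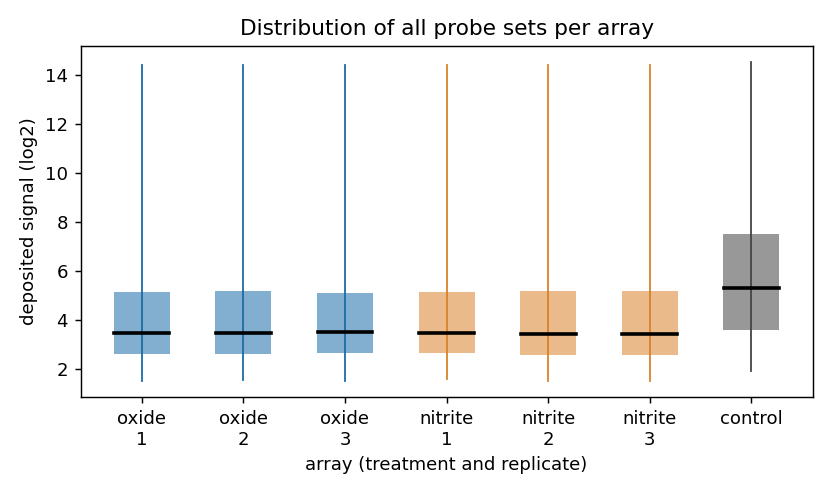
Deposited log2 signal of all probe sets on each array, by treatment and replicate: box, interquartile range; black line, median; thin line, lowest to highest value. The 6 treated medians lie between 3.41 and 3.48, and the control median is 5.30.

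Both arrays numbered 3 differed from the other treated arrays in control signals. The mean poly-A spike signal was 4.99 (graphene oxide) and 5.19 (graphene nitrite) on these arrays, against 6.18 to 6.57 on the other 4 treated arrays and 5.28 on the control array. The log2 difference between the 3' and 5' probe sets of ACTB, a cytoskeletal actin, was 4.07 and 3.83 on them, 2.79 to 3.12 on the other 4 and 3.11 on the control array. For GAPDH, a glycolytic enzyme, it was 1.27 and 1.01 against 0.65 to 0.75, with 0.58 on the control array. The same difference averaged over the poly-A spikes, which are added to the RNA after extraction, was 3.89 and 3.74 against 3.01 to 3.32, with 3.02 on the control array.

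**Figure D2:**
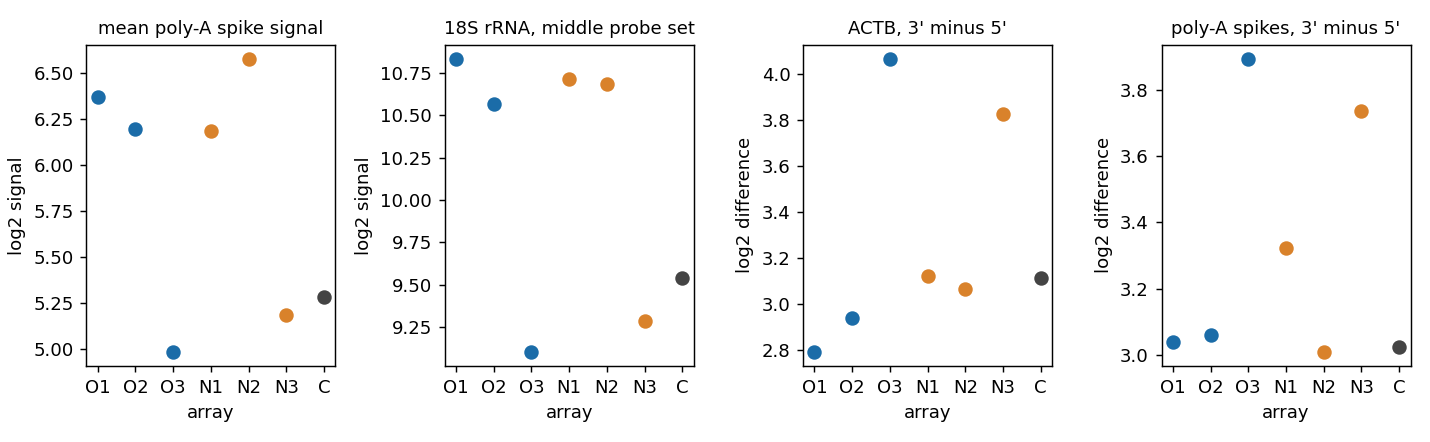
Control signals on each array (O, graphene oxide; N, graphene nitrite; C, control; digits, replicates), in log2 units: mean poly-A spike signal, signal of the middle 18S rRNA probe set, and 3' minus 5' differences of ACTB and of the poly-A spikes. Each point is 1 array. Replicate 3 of both treatments has spike means of 4.99 and 5.19, below the 6.18 to 6.57 of the other 4 treated arrays.

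Genes that mark luminal, estrogen-responsive breast cells had signals from below the background mean to the upper part of all genes. The fixed list of estrogen receptor targets had a median percentile of 53.2 on the treated arrays and 52.1 on the control array, and the luminal and epithelial list 61.4 and 55.6. FOXA1 lay at percentiles 77.9 and 83.5, XBP1 at 74.6 and 88.4 and GATA3 at 58.8 and 67.3, all transcription factors of luminal cells. ESR1, the estrogen receptor, was at 4.38 ± 0.08 (SD, n = 6) on the treated arrays and 4.47 on the control array, at percentiles 52.5 and 31.5 of all genes. The estrogen-induced genes TFF1 and TFF3 were at 2.70 ± 0.10 and 2.21 ± 0.07 on the treated arrays (SD, n = 6), below the treated background mean of 2.93, and at 3.61 and 2.69 on the control array. PGR, the progesterone receptor, was at 2.81 ± 0.17 and 2.94, and GREB1, a cofactor of the estrogen receptor, at 3.08 ± 0.22 and 4.24. The epithelial keratins KRT8, KRT18 and KRT19 and the adhesion molecule EPCAM lay at percentiles 93.8 to 97.6 on the treated arrays (mean signals 8.07 to 9.29) and 90.7 to 95.2 on the control array (9.70 to 10.42). VIM, an intermediate filament of mesenchymal cells, was at 11.30 ± 0.24 and 12.83, and CDKN2A, a cell cycle inhibitor, at 6.79 ± 0.23 and 8.97. These single genes were chosen after their values were seen, and the control values lie on the control array's own scale.

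**Figure D3:**
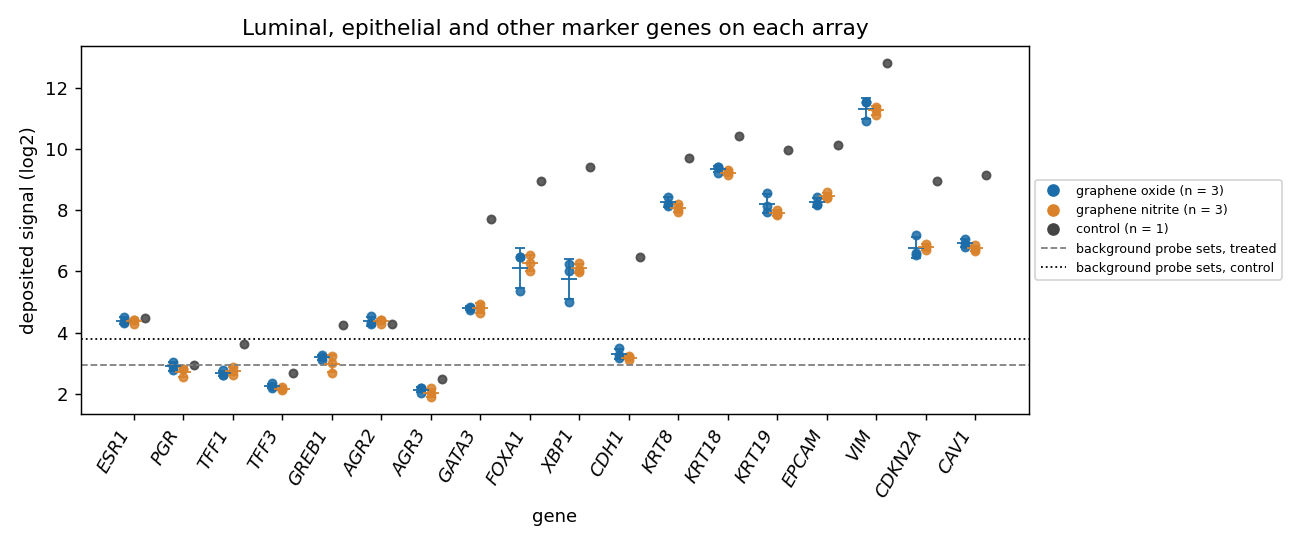
Deposited log2 signal of luminal (ESR1 to CDH1), epithelial (KRT8 to EPCAM) and other marker genes (VIM, CDKN2A, CAV1) on each array. Points, single arrays; bars, mean ± SD of 3 arrays; lines, mean of the background probe sets on the treated (2.93) and control (3.78) arrays. TFF1 and TFF3 lie at 2.70 and 2.21 on the treated arrays, and VIM at 11.30.

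In cells given graphene oxide, the deposited signals of single interferon and stress genes were far lower than on the control array. IFIT1, which binds viral RNA, fell by 6.06 (log2; SE 0.18, n = 3 against 1, limma adjusted p = 5.6e-07), and RIGI, a sensor of viral RNA, fell by 5.29 (SE 0.13). HMOX1, the heme-degrading enzyme of the oxidative stress response, fell by 5.88 (SE 0.19). GDF15, a secreted stress cytokine, fell by 5.64 (SE 0.14) and BRCA1, a DNA repair gene, by 5.39 (SE 0.31). Among the genes that rose, MSMO1, an enzyme of cholesterol synthesis, gained 2.66 (SE 0.43) and the linker histone gene H1-2 gained 1.76 (SE 0.10). HTR2A, a serotonin receptor, was at 5.30 ± 0.16 (SD, n = 3) against 3.01 on the control array, which is under that array's background mean of 3.78, so its rise is given from that background, as at least 1.52. These genes passed the threshold in the same direction after both other scalings, which shrank the falls and enlarged the rises. IFIT1 changed by -4.23 after centring and -3.90 after quantile normalization, MSMO1 by 4.49 and 4.91, and H1-2 by 3.60 and 3.98. After quantile normalization the changes were -3.71 for HMOX1, -3.49 for GDF15, -3.17 for BRCA1 and -3.06 for RIGI.

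The other large falls under graphene oxide as deposited were IRF9 (-5.56), part of the interferon-activated transcription factor, C6orf120 (-5.50), GNE (-5.42), an enzyme of sialic acid synthesis, TBC1D9 (-5.35), MRTFB (-5.28), a coactivator of SRF, RABEP1 (-5.13) and SLC35B3 (-5.07). After quantile normalization these falls were -3.36, -3.34, -3.21, -3.11, -3.05, -2.87 and -2.83 in the same order. The other large rises were ANKRD37 (2.00 as deposited and 3.74 after quantile normalization), H2BC21 (1.82 and 4.09), CCDC69 (1.78 and 3.22) and PSG6 (1.60 and 3.02). Those of POM121L8P (at least 1.85), BASP1-AS1 (at least 1.24), FGF7P3 (at least 1.15), FGF7 (at least 0.86) and CCDC144A (at least 0.45) started below the control background of 3.78 and are counted from it. On the treated arrays IFIT1 (3.24 ± 0.06, SD, n = 3), RIGI (3.21 ± 0.01), BRCA1 (3.30 ± 0.48), MRTFB (3.23 ± 0.13), GNE (3.25 ± 0.43) and SLC35B3 (3.35 ± 0.49) lay near the background mean of 2.93, so the size of their falls may be bounded by the background. FGF7 and FGF7P3, and POM121L8P and its relatives, are near-identical copies whose probes may not tell them apart. All 5 probe sets of BRCA1, 3 of HMOX1, 4 of IRF9 and 4 of HTR2A moved the same way as deposited. For falls this says little, because only 367 of 10879 genes lay above 0 as deposited. After quantile normalization all these probe sets kept their direction. Their changes then ranged from -3.17 to -0.45 for BRCA1, -3.71 to -1.72 for HMOX1, -3.36 to -0.50 for IRF9 and 1.12 to 3.26 for HTR2A. Among other genes that rose as deposited, only 1 of 3 probe sets was higher for H2BC21, 1 of 2 for ANKRD37, 2 of 4 for MSMO1, 1 of 3 for CCDC69, 1 of 3 for FGF7 and 2 of 3 for PSG6. After quantile normalization, which raises most values against the control, these counts were 1, 2, 4, 2, 2 and 3. For GDF15 all 5 probe sets were lower as deposited, but 3 of 5 after quantile normalization, and for GNE, MRTFB and SLC35B3 all 3 as deposited, but 2 of 3. CCDC69 was lower, not higher, when its probe sets were averaged (-0.65).

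As deposited, 117 genes were higher and 9974 lower in graphene oxide than in control, out of 10879 tested (limma, adjusted p under 0.05). This split depended on the scale of the control array. After median centring 2693 genes were higher and 4021 lower, and after quantile normalization 3687 were higher and 2278 lower, so the share of higher calls went from 1.16% to 40.1% and 61.8%. On the quantile scale background probe sets of high GC count were also higher on the treated arrays, although they match no transcript. Control minus treated was -0.71 at a GC count of 21 and -1.12 at 23, but 0.06 at 10. In all 3 scalings, 117 genes were higher and 2200 lower. The deposited scale bars most rises from this count, so its excess of falls is no result about the cells.

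**Figure D4:**
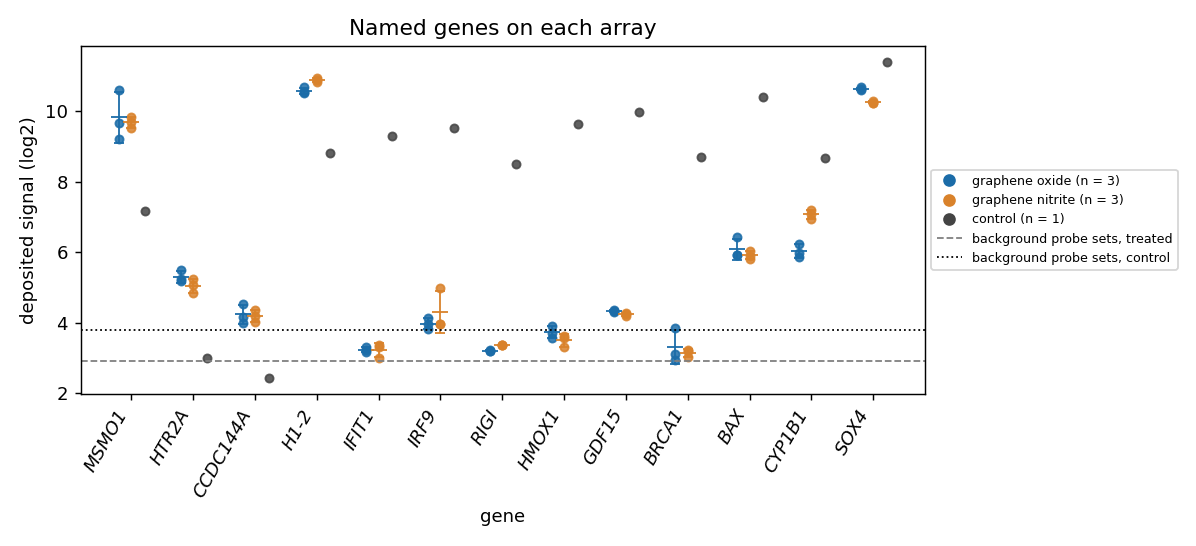
Deposited log2 signal of named genes on each array. Points, single arrays; bars, mean ± SD of 3 arrays; lines, mean of the background probe sets on the treated (2.93) and control (3.78) arrays. MSMO1, HTR2A, CCDC144A and H1-2 lie above the control array in both treatments, IFIT1, RIGI and BRCA1 lie between 3.15 and 3.37 on average in both treatments, and CYP1B1 and SOX4 are the genes of lowest p between the treatments.

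Counts in a list have to be read against all 10879 genes, of which 9974 were lower as deposited and 2200 in all 3 scalings. After quantile normalization 3687 of all genes were higher and 2278 lower. Interferon-response genes went in both directions under graphene oxide once the scale was changed. Of 18 tested, 15 were lower and 0 higher as deposited, 12 were lower and 5 higher after centring, 10 were lower and 5 higher after quantile normalization, and 10 were lower in all 3 scalings. ISG15, a ubiquitin-like protein, changed by -4.59 as deposited and -2.59 after quantile normalization, and IFI6 by -4.92 and -2.76. The list lay below other genes after quantile normalization (camera adjusted p = 0.0094, adjusted p = 0.61 with an estimated correlation), but not as deposited (adjusted p = 0.45) or after centring (adjusted p = 0.10).

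Targets of p53, the tumour suppressor, were lower in 19 of 19 cases as deposited, in 10 with 1 higher after quantile normalization, and in 10 in all 3 scalings. ZMAT3, an RNA-binding protein, changed by -4.71 as deposited and -2.42 after quantile normalization, BAX, which promotes apoptosis, by -4.31 and -2.20, and TP53I3 by -3.66 and -1.42. The camera adjusted p was 0.0048 after quantile normalization (adjusted p = 0.61 with an estimated correlation) and 0.24 as deposited. Genes of the ATF4 amino acid response, which copes with amino acid shortage, were lower in 23 of 23 cases as deposited, in 10 with 3 higher after quantile normalization, and in 9 in all 3 scalings. Of these, PHGDH, the first enzyme of serine synthesis, changed by -2.89 and -1.07, and DDIT3, a stress transcription factor, by -3.06 and -0.70. The camera adjusted p was 0.0085 after quantile normalization (adjusted p = 0.61 with an estimated correlation) and 0.45 as deposited.

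Genes of the fixed list of replication-dependent histones stood above other genes under graphene oxide. Of 9 tested, 3 were higher and 2 lower as deposited, 8 were higher and 1 lower after quantile normalization, and 3 were higher in all 3 scalings. H2BC21 rose by 1.82 (SE 0.32) as deposited and 4.09 after quantile normalization, with 1 of its 3 probe sets higher on each scale. H2BC12 changed by -1.39 as deposited and 0.45 after quantile normalization, and H4C3 by -1.36 as deposited, -0.29 after quantile normalization and 0.48 after centring, so both reversed with the scaling. The camera adjusted p was 3.9e-14 as deposited (adjusted p = 0.18 with an estimated correlation) and 0.0081 after quantile normalization (adjusted p = 0.61 with an estimated correlation).

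Genes of cholesterol biosynthesis also stood above other genes. Of 18 tested, 3 were higher and 14 lower as deposited, 14 were higher and 0 lower after quantile normalization, and 3 were higher in all 3 scalings. MSMO1 was among the 3, while NSDHL, which acts in the same demethylation steps, changed by -1.86 as deposited, -0.02 after centring and 0.50 after quantile normalization, and DHCR7 by -2.32, -0.48 and 0.07. SC5D changed by -2.66 as deposited and -0.34 after quantile normalization, where its adjusted p was 0.087 and 3 of its 4 probe sets were lower. The camera adjusted p was 6.0e-04 as deposited (adjusted p = 0.23 with an estimated correlation) and 0.0048 after quantile normalization (adjusted p = 0.61 with an estimated correlation).

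The oxidative stress genes controlled by NRF2 went in both directions after quantile normalization. All 20 tested were lower as deposited, but 5 were higher and 6 lower after quantile normalization, and 5 were lower in all 3 scalings. Besides HMOX1, SQSTM1, an autophagy receptor, changed by -3.59 as deposited and -1.55 after quantile normalization. PRDX1, a peroxidase, changed by -1.54 as deposited, -0.12 after quantile normalization and 0.30 after centring, and TXN, thioredoxin, by -1.58, -0.36 and 0.26, so both turned with centring. The camera adjusted p was 0.18 as deposited and 0.36 after quantile normalization, where fry, which tests a list's own change, called the list lower (adjusted p = 0.033).

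Among 20 DNA repair genes, all were lower as deposited and 4 in all 3 scalings, where 9974 and 2200 of all 10879 genes were. BRCA1 changed by -3.17 after quantile normalization, and ATR, a damage-signalling kinase, by -4.23 as deposited and -1.97 after quantile normalization. BARD1, the partner of BRCA1, changed by -1.17 after centring and -0.64 after quantile normalization. Of 25 targets of breast cancer imaging and therapy, 22 were lower and 0 higher as deposited, 8 were higher and 6 lower after quantile normalization, and 6 were lower in all 3 scalings. MET, a growth factor receptor, changed by -4.68 as deposited and -2.39 after quantile normalization, with 3 of its 6 probe sets in that direction after quantile normalization. CDK6, a cell cycle kinase, changed by -3.73 and -1.45, while EGFR, the epidermal growth factor receptor, changed by -2.60 and by -0.24 after quantile normalization, where its adjusted p was 0.25 and 4 of its 8 probe sets were lower. Neither list passed the camera test as deposited (adjusted p = 0.37 and 0.56) or after quantile normalization (adjusted p = 0.59 and 0.96).

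Hypoxia-response genes were above other genes as deposited (camera adjusted p = 0.018, adjusted p = 0.63 with an estimated correlation) but not after quantile normalization (adjusted p = 0.25). Of 21 tested, 1 was higher and 16 lower as deposited, and 10 were higher and 2 lower after quantile normalization. EGLN1, an oxygen sensor, changed by -3.02 as deposited and -0.66 after quantile normalization, and VEGFA, a growth factor for vessels, by -2.65 and -0.57. After quantile normalization 1 of the 3 probe sets of EGLN1 was lower, and 1 passed an unadjusted p of 0.05 in the opposite direction. For VEGFA 4 of 10 were lower, 3 of them past it, and 4 passed it in the opposite direction. Glycolysis genes, with 11 of 17 lower as deposited and 11 higher and 0 lower after quantile normalization, turned with the scaling. They stood above other genes on both (camera adjusted p = 6.2e-04 and 0.0081, adjusted p = 0.63 and 0.62 with an estimated correlation). Ribosomal protein genes, with 28 of 28 lower as deposited and 5 higher and 13 lower after quantile normalization, were called lower by camera on both (adjusted p = 6.0e-04 and 0.0094, adjusted p = 0.50 and 0.61 with an estimated correlation), but higher after median centring, with 26 of 28 higher (adjusted p = 9.4e-14, and adjusted p = 0.66 with an estimated correlation). The sign of their median relative to all genes, 1.12 as deposited, differed from that test.

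For the remaining lists under graphene oxide, the calls as deposited were of the same kind. Metallothioneins (4 of 7 lower), AP-1 and immediate early genes (21 of 27 lower) and leukocyte markers (2 of 4 lower) stood above other genes, each with a camera adjusted p of 0.0086 and adjusted p values of 0.50, 0.38 and 0.50 with an estimated correlation. After quantile normalization their adjusted p values were 0.13, 0.19 and 0.10. Oxidative phosphorylation genes (30 of 30 lower, adjusted p = 0.012, and adjusted p = 0.63 with an estimated correlation) were called lower than other genes, although their median relative to all genes was 0.37, and had an adjusted p of 0.29 after quantile normalization and of 0.38, with the direction turned, after centring. Ribosome biogenesis genes (26 of 26 lower, 12 in all 3 scalings) had an adjusted p of 0.085 as deposited and 0.0094 after quantile normalization (adjusted p = 0.61 with an estimated correlation). Counts of lower genes as deposited were 32 of 33 for G2/M and mitosis, 32 of 32 for G1/S and DNA replication, 16 of 17 for heat shock, 19 of 19 for the unfolded protein response, 12 of 15 for estrogen receptor targets, 7 of 9 for fatty acid synthesis, 10 of 13 for NF-kB and inflammation, and 5 of 6 for AhR targets. They were 24 of 25 for autophagy and lysosome, 21 of 22 for apoptosis regulators, 13 of 17 for luminal identity, 10 of 10 for mesenchymal genes, 16 of 18 for cytoskeleton and SRF targets, 2 of 4 for basal markers and 2 of 3 for endothelial and adipocyte markers. None of these 15 lists passed the camera test on either scale, and fibroblast markers had 1 gene tested. Adjusted over the list alone, the counts as deposited were the same for every list except the histones (2 higher and 2 lower).

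**Figure D5:**
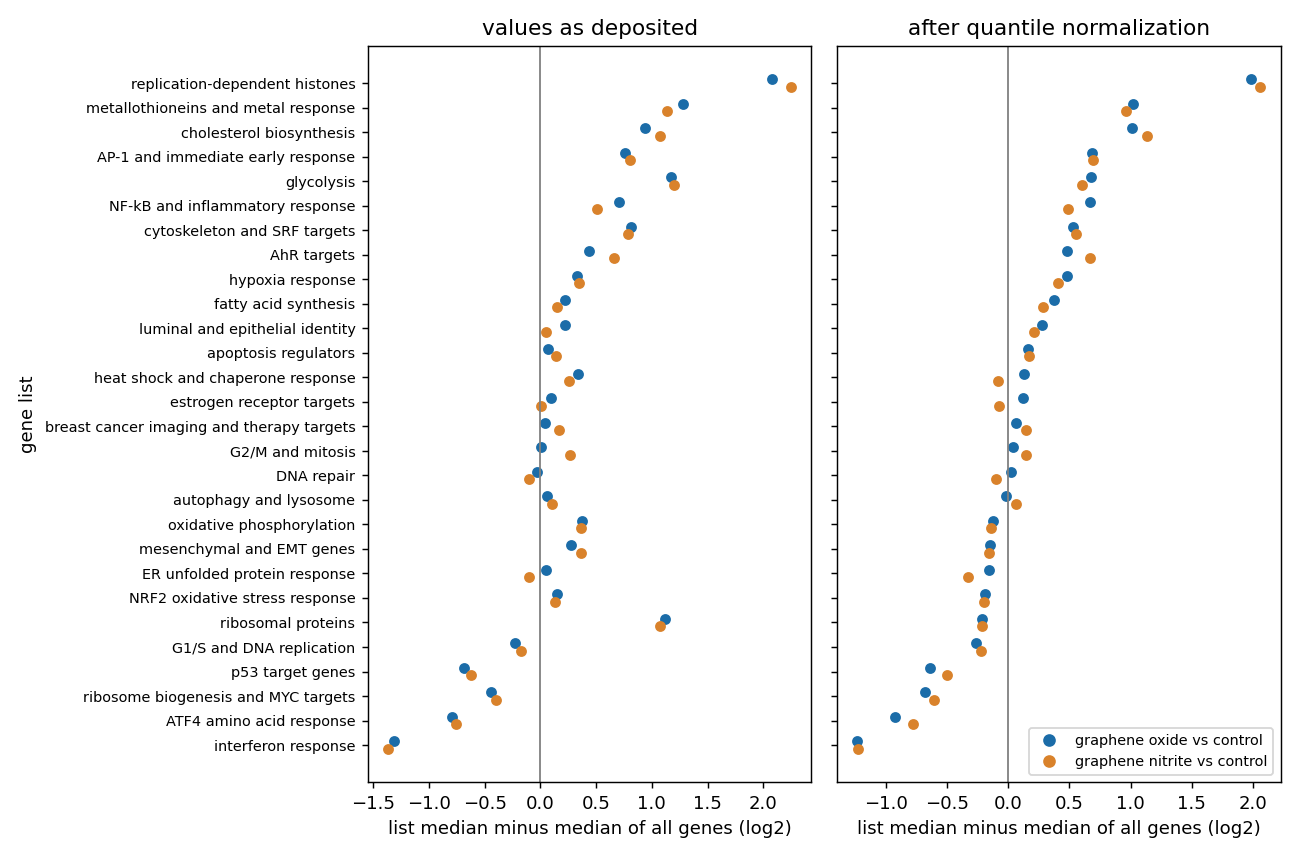
Median log2 change of each pathway list against control, minus the median of all genes tested, for graphene oxide (blue) and graphene nitrite (orange), as deposited and after quantile normalization. Each point is 1 list. The histone list has the highest median on both scales for graphene oxide (2.08 and 1.98), and the interferon list the lowest (-1.31 and -1.23).

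In cells given graphene nitrite, single stress and interferon genes were likewise among the largest falls as deposited. HMOX1 fell by 6.12 (log2; SE 0.19, n = 3 against 1, limma adjusted p = 5.4e-07), IFIT1 by 6.07 (SE 0.18), GDF15 by 5.73 (SE 0.14) and BRCA1 by 5.55 (SE 0.31). The interferon genes RIGI, IRF9 and IFI6 fell by 5.13 (SE 0.13), 5.23 (SE 0.38) and 5.14 (SE 0.18). MSMO1 rose by 2.52 (SE 0.43), H2BC21 by 2.08 (SE 0.32) and H1-2 by 2.06 (SE 0.10), while HTR2A, under the background on the control array, rose by at least 1.26. After quantile normalization the changes were -3.94 for HMOX1, -3.89 for IFIT1, -3.58 for GDF15, -3.32 for BRCA1, -2.86 for RIGI, -3.01 for IRF9, -2.98 for IFI6, 4.75 for MSMO1, 4.29 for H2BC21 and 4.27 for H1-2.

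Other rises under graphene nitrite as deposited were ANKRD37 (2.18, and 3.86 after quantile normalization), CCDC69 (1.69 and 3.10, but -0.70 as deposited when averaged over its probe sets) and ZNF658 (1.60 and 3.26), a zinc finger gene. Counted from the control background of 3.78, under which their control signals lay, POM121L8P rose by at least 1.67, BASP1-AS1 by at least 1.10, CACNA1A by at least 1.02, FGF7 by at least 0.91 and CCDC144A by at least 0.40. As deposited, 1 of 3 probe sets moved that way for H2BC21, CCDC69 and FGF7, 2 of 3 for CACNA1A, 1 of 2 for ANKRD37 and 2 of 4 for MSMO1, while after quantile normalization it was all of them for each of these genes except CCDC69 (2 of 3). Other falls were GNE (-5.49 as deposited and -3.26 after quantile normalization), MRTFB (-5.31 and -3.05), TBC1D9 (-5.28 and -3.02), C6orf120 (-5.27 and -3.10) and RABEP1 (-5.19 and -2.92). With treated signals of 3.15 to 3.37 on average, near the background mean, the falls of IFIT1, RIGI, BRCA1, GNE and MRTFB may be bounded by the background here too. As deposited 106 genes were higher and 10024 lower out of 10879. After median centring 2742 were higher and 3711 lower, and after quantile normalization 3667 were higher and 2227 lower, so the share of higher calls went from 1.05% to 42.5% and 62.2%. In all 3 scalings 106 were higher and 2135 lower, with most rises again barred by the deposited scale.

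Of 18 interferon-response genes under graphene nitrite, 16 were lower as deposited, 11 were lower and 5 higher after quantile normalization, and 11 were lower in all 3 scalings (camera adjusted p = 0.42 as deposited and 0.0086 after quantile normalization, the latter with adjusted p = 0.57 with an estimated correlation). ISG15 changed by -4.73 as deposited and -2.79 after quantile normalization. Of all 10879 genes, 10024 were lower as deposited and 2135 in all 3 scalings, against which the list counts have to be read. Of 9 histone genes, 3 were higher in all 3 scalings (camera adjusted p = 1.4e-17 as deposited, adjusted p = 0.12 with an estimated correlation, and 0.0086 after quantile normalization, adjusted p = 0.55 with an estimated correlation). H2BC12 changed by -1.07 as deposited, 0.79 after centring and 0.73 after quantile normalization, and H4C3 by -1.36, 0.49 and -0.33. Of 18 cholesterol synthesis genes, 3 were higher and 14 lower as deposited and 14 higher and 0 lower after quantile normalization (camera adjusted p = 8.7e-05 and 0.0021, adjusted p = 0.16 and 0.55 with an estimated correlation). NSDHL, lower as deposited, changed by 0.05 after centring and 0.53 after quantile normalization, and DHCR7 by -2.09 as deposited, -0.23 after centring and 0.26 after quantile normalization.

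Targets of p53 under graphene nitrite were lower in 19 of 19 cases as deposited and in 8 in all 3 scalings, with BAX at -4.48 as deposited and -2.40 after quantile normalization. ATF4-response genes were lower in 23 of 23 cases and in 9 in all 3 scalings, with PHGDH at -2.81 and -1.06. The camera adjusted p after quantile normalization was 0.0086 for p53 targets and 0.020 for ATF4-response genes (adjusted p = 0.57 for both with an estimated correlation), against 0.31 and 0.69 as deposited. All 20 NRF2-controlled genes were lower as deposited, 5 were higher and 5 lower after quantile normalization (fry adjusted p = 0.034, lower) and 4 were lower in all 3 scalings, with SRXN1, which repairs peroxidases, at -3.12 and -0.82, and PRDX1 at -1.52 as deposited but 0.33 after centring. MET changed by -4.90 and -2.62, with 2 of its 6 probe sets lower after quantile normalization, and CDK6 by -4.00 and -1.72, among 23 of 25 imaging and therapy targets that were lower as deposited and 7 in all 3 scalings.

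As deposited, 9 lists passed the camera test in each treatment, 7 above and 2 below other genes, and 0 passed with an estimated correlation in either (3 at an unadjusted p under 0.05). Without graphene oxide replicate 3 the lists were 3 above and 3 below for graphene oxide, and 5 above and 4 below for graphene nitrite. For graphene nitrite the others were hypoxia response (adjusted p = 0.0081), glycolysis (2.8e-04), AP-1 and immediate early genes (0.0031), metallothioneins (0.036), leukocyte markers (0.021), oxidative phosphorylation (0.012) and ribosomal proteins (3.8e-04). Their adjusted p values with an estimated correlation were 0.50, 0.59, 0.26, 0.50, 0.50, 0.61 and 0.50. After quantile normalization only glycolysis (0.010) and ribosomal proteins (0.016) of these 7 passed (adjusted p = 0.61 and 0.57 with an estimated correlation), and hypoxia response was at 0.19, AP-1 and immediate early genes at 0.15, metallothioneins at 0.15, leukocyte markers at 0.12 and oxidative phosphorylation at 0.21. The lists called below other genes were oxidative phosphorylation and ribosomal proteins, whose medians relative to all genes (0.36 and 1.07) had the opposite sign. After centring, ribosomal proteins were called above other genes (adjusted p = 8.5e-14, and adjusted p = 0.68 with an estimated correlation), with 26 of 28 higher, and oxidative phosphorylation turned without passing (0.34). Adjusted over the list alone, counts for graphene nitrite as deposited differed for the histones (2 higher and 2 lower), AP-1 and immediate early genes (20 lower) and autophagy and lysosome (25 lower).

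Fold changes against the control were alike in both treatments, across genes, which are not independent replicates. Pearson's r was 0.988 across 10879 genes as deposited and 0.985 after quantile normalization, where unchanged groups simulated against 1 shared control gave 0.750 on both. The covariance was 1.04, against 0.036 in the simulation. As deposited 99 genes were higher and 9919 lower in both treatments and 0 went in opposite directions, where independent lists of these sizes would share 1.14 and 9190. After quantile normalization 3445 were higher and 2026 lower in both, where independent lists would share 1243 and 466. Independent lists are no fair baseline here, because both comparisons use the same control array. The simulation, with its covariance of 0.036, did not carry that array's departure from the treated arrays. The single control array could not be split, so part or all of the likeness may come from it.

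Between the materials, no gene differed past the threshold. CYP1B1, a cytochrome P450 controlled by the aryl hydrocarbon receptor, had the lowest p, with 7.07 ± 0.13 in graphene nitrite and 6.03 ± 0.19 in graphene oxide (SD, n = 3), a difference of 1.04 (SE 0.14, limma adjusted p = 0.62), and 4 of its 5 probe sets were higher. SOX4, a developmental transcription factor, was at 10.25 ± 0.03 in graphene nitrite and 10.63 ± 0.03 in graphene oxide (SD, n = 3), a difference of -0.39 (SE 0.06, adjusted p = 0.70), and all 7 probe sets were lower. Higher values in graphene nitrite, not past the threshold, were those of CPE (0.45), ZNF200 (0.43), H2AX (0.40) and H1-2 (0.30), and lower ones those of APOC1P1 (-0.52), SLC17A9 (-0.49), CTDSP1 (-0.45) and STK10 (-0.44). With limma, 0 genes passed an adjusted p of 0.05 and 330 an unadjusted p under 0.05, out of 10879. The latter count was 618 without graphene oxide replicate 3, 532 without graphene oxide replicate 2 and 144 without graphene nitrite replicate 2. With array weights, CYP1B1 (adjusted p = 0.0054, where the highest over the alternatives was 0.999) and SOX4 (adjusted p = 0.015, likewise up to 0.999) passed, in a fit that gave graphene oxide replicate 1 a weight of 5.51 and replicate 3 a weight of 0.18.

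For 10650 of the 10879 genes (97.9%), the 95% interval of the difference between the materials lay within a 2-fold change. Groups did not overlap in 1037 genes (9.53%), where chance gives 10%. No gene of the G2/M list passed between the materials, but 32 of 33 values lay above 0 in graphene nitrite, with a median of 0.18. Their fry adjusted p, for the list's own change, was 0.61. Their camera adjusted p was 9.0e-09 (1.9e-07 after quantile normalization), and adjusted p = 0.95 with an estimated correlation (0.27 after quantile normalization). KIF23, a kinesin of cell division, differed by 0.42 (SE 0.12), ECT2 by 0.38 (SE 0.12), CDK1, the mitotic kinase, by 0.28 (SE 0.09) and PRC1 by 0.23 (SE 0.08), with 2 of 2, 2 of 2, 2 of 3 and 2 of 4 of their probe sets higher, each with an adjusted p of 0.99 over all genes. The histone list had a median of 0.17 and a camera adjusted p of 0.044 (0.061 after quantile normalization, adjusted p = 0.95 with an estimated correlation, and 0.96 by fry), with H2BC12 at 0.32 (SE 0.10), where 1 of its 2 probe sets was higher. Adjusted over the list alone, 1 histone gene (H1-2) and 1 AhR target (CYP1B1) were higher, and 0 genes of any other list passed. The number of lists past the threshold, 2, was 8 without graphene oxide replicate 3 and 5 without graphene oxide replicate 2.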

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

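The test on probe sets of 1 gene was set before its result was seen, while the tests on scale, RNA degradation, olfactory receptor genes and spike signals were chosen after.

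Some control probe sets, which enter no comparison, gave signals above the control array on 4 of the treated arrays. The mean of the hybridization spikes was above it on all 6 treated arrays, with 10.53 to 11.28 against 10.24. The background probe sets were below it on all 6, with means of 2.86 to 2.98 against 3.78. The mean poly-A spike signal was 6.37 and 6.20 on graphene oxide replicates 1 and 2 and 6.18 and 6.57 on graphene nitrite replicates 1 and 2, against 5.28 on the control array. The middle probe set of 18S rRNA was at 10.83 and 10.57 on graphene oxide replicates 1 and 2 and at 10.72 and 10.69 on graphene nitrite replicates 1 and 2, against 9.54 on the control array. The 3' probe set of 18S rRNA went the other way, with 12.10 on the control array and at most 10.09 on the treated arrays.

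Both arrays numbered 3 had larger differences between 3' and 5' probe sets than the other treated arrays, in ACTB (4.07 and 3.83 against at most 3.12) and GAPDH. Degraded cell RNA as the whole cause is argued against by the poly-A spikes, added after extraction, whose mean 3' minus 5' difference was higher on both arrays than on any other treated array, by at least 0.41. Most of this comes from the dap spike (6.09 and 5.78 against at most 4.04); phe (2.12 and 2.16 against at most 2.09) and lys (1.95 and 2.02 against at most 1.84) were higher by little, and thr (5.40 and 4.98 against up to 5.64) was not. A separate labelling batch is a candidate explanation, since the mean spike signal of both lay below that of every other treated array, by at least 0.995. The control array, numbered 3 in its source name, had a low spike signal too (5.28) but a mean spike 3' minus 5' difference of 3.02, like the replicates numbered 1 and 2. No biological explanation was tested, because both treatments show the pattern.

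The control array stood apart from all 6 treated arrays, with correlations of 0.870 to 0.895. A difference of overall scale as the whole cause is argued against by the 5965 genes that passed the threshold for graphene oxide after quantile normalization. Degraded control RNA stays open, because its measures disagree. The 3' minus 5' difference of the control array was 3.11 for ACTB, within the 2.79 to 3.12 of the 4 treated arrays not numbered 3, and 0.58 for GAPDH, below their 0.65 to 0.75, but 2.65 for 18S rRNA, above the 0.35 of the highest treated array. A technical difference that moves single probe sets stays open as well, because 23.9% of 2368 genes with several called probe sets had calls in opposite directions, between the bounds of 10% and 25% set for this test and below the 58.2% of independent probe sets. Background probe sets, which match no transcript, still differed after quantile normalization. Control minus treated was 0.06 and 0.12 at GC counts of 10 and 16, but -0.71, -1.08, -1.12, -1.11 and -0.81 at 21 to 25. A technical difference thus remained on that scale, of unknown extent for genes. Of 333 olfactory receptor genes, which most cells leave silent, 151 (45.3%) were called for graphene oxide after quantile normalization, 150 of them higher, against 50.2% of all genes. An effect shared by both treatments stays open too, untested, because 1 control array may also have been handled or normalized apart from the others.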

How the results depend on the processing

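All combinations with quantile normalization beyond quantile normalization itself, and the batch term, were chosen after the results were seen. Among named genes against the control, 1756 of the values recomputed kept direction and call, 23 lost the call and 18 changed direction. Between the treatments, 299 values did not change side and 2 passed the threshold. Of the list results, 216 kept direction and call, 66 lost the call and 16 changed direction. The correlation of fold changes between the treatments lay between 0.980 and 0.992 in all its alternatives, a change smaller than the SD of r over the 9 pairs of single arrays (0.022), whose own r was 0.928 to 0.985. What the arrays limit is signal over background: falls to the level of the background probe sets are bounded by it.

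Without the filter, which tests more genes, 15845 genes passed for graphene oxide and 15991 for graphene nitrite against control, and with each probe set alone 24855 and 25008. On the same genes, only alternatives that changed the scaling moved these counts by over 1.5 times: 5965 and 5894 after quantile normalization, 6714 and 6453 after median centring, 6397 and 6291 after quantile normalization with the batch term, 5154 and 5057 after quantile normalization with a 1.5-fold minimum, and 2317 and 2241 in all 3 scalings. Quantile normalization without graphene oxide replicate 3 gave 7134 and 7441. Of the deposited calls, 2395 (graphene oxide) and 2333 (graphene nitrite) kept their direction after quantile normalization and 2797 and 2830 turned. The cause of the control array's scale was not tested here. Leaving out each treated array gave 9956 to 10217 genes for graphene oxide and 10002 to 10255 for graphene nitrite. Between the treatments 2 genes passed with array weights, 1 higher and 1 lower, and the cause was not tested.

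Genes that changed direction did so with the scaling or the probe sets, for causes that were not tested further. After quantile normalization DHCR7 was at 0.067 and 0.26 (graphene oxide and nitrite), H2BC12 at 0.45 and 0.73, and NSDHL at 0.50 and 0.53. After median centring H2BC12 was at 0.45 and 0.79, H4C3 at 0.48 and 0.49, PRDX1 at 0.30 and 0.33, TXN at 0.26 under graphene oxide and NSDHL at 0.054 under graphene nitrite. CCDC69 was at -0.65 and -0.70 as the mean of its probe sets and at -0.67 and -0.73 as their median with each tested alone.

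For lists against control, 9 passed in each treatment. For graphene oxide 14 passed without the filter, 0 with an estimated correlation, 29 by fry in 1 direction and 30 by fry in either, and for graphene nitrite 0, 29 and 31. Without graphene oxide replicate 3 the lists above other genes went from 7 to 3 for graphene oxide (6 lists in all) and to 5 for graphene nitrite (9 in all). Fry tests a list's own change, so lists above other genes but below the control were called lower: metallothioneins (adjusted p = 0.0037 and 0.0012), cholesterol biosynthesis (2.7e-05 and 3.6e-05), hypoxia response (6.4e-04 and 4.8e-04), glycolysis (0.028 and 0.018), AP-1 and immediate early genes (6.8e-05 and 8.3e-05), with leukocyte markers at 0.097 and 0.053. After median centring camera put ribosomal proteins above other genes (9.4e-14 and 8.5e-14, but 0.66 and 0.68 with an estimated correlation). The direction for oxidative phosphorylation turned without passing (0.38 and 0.34). Centring moves the change of every gene by the same amount. For graphene oxide the medians relative to all genes stayed at 1.12 (ribosomal proteins) and 0.37 (oxidative phosphorylation). The turns therefore came from the control array's offset, which the camera calls as deposited carry. Between the treatments 2 lists passed, but 4 with the mean over probe sets, 1 after quantile normalization, 0 with an estimated correlation, 0 by fry in 1 direction and 1 in either, and 2 to 8 when single arrays were left out, with 5 without graphene oxide replicate 2 and 8 without replicate 3. The cause was not tested.

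Across genes, same-numbered arrays of the treatments did not deviate together more than differently numbered ones (r of -0.00, 0.13 and 0.11 against -0.22 to 0.26). The numbers were therefore not taken to pair the samples, although both arrays numbered 3 shared low spike signals. With the number as a replicate block, 9892 genes passed for graphene oxide and 9961 for graphene nitrite against control, 9851 and 9920 of them shared with the unblocked calls and 0 in the opposite direction, and 0 between the treatments (329 at an unadjusted p under 0.05), where 1 list passed. With the control as number 1 the counts were 9950 and 10003. Across the treatments, 3 of the 6 arrays correlated best with the array of their own number.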

Other observations

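The tests on luminal genes and on splits of the arrays in this part were chosen after the results were seen.

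Marker genes of other cell types differed in signal. Of 8 basal or keratinocyte markers measured, CAV1, a membrane protein of caveolae, was highest, at 6.92 ± 0.13 (SD, n = 3) under graphene oxide, 6.76 ± 0.09 under graphene nitrite and 9.16 on the control array, followed by SFN (4.94 ± 0.06, 5.04 ± 0.13 and 6.29) and KRT14 (4.71 ± 0.08, 4.65 ± 0.22 and 4.91). Of 11 fibroblast markers, FBN1, a matrix fibrillin, was highest, at 4.78 ± 0.01, 4.76 ± 0.12 and 7.01, while COL1A1 was at 3.84 ± 0.46, 3.82 ± 0.42 and 3.24 and PDGFRB at 3.62 ± 0.08, 3.63 ± 0.45 and 4.23. Of 14 leukocyte markers, TYROBP was at 5.72 ± 0.17, 5.46 ± 0.11 and 5.66, CORO1A at 4.63 ± 0.28, 4.27 ± 0.08 and 5.37, and CD3E at 3.90 ± 0.38, 4.12 ± 0.15 and 4.33. Of 10 endothelial and adipocyte markers, PECAM1 was at 4.79 ± 0.05, 4.53 ± 0.30 and 4.71, LPL at 4.54 ± 0.15, 4.71 ± 0.16 and 7.43, and VWF at 4.27 ± 0.03, 4.25 ± 0.05 and 5.39.

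The measured estrogen receptor targets, 23 genes, had a median percentile of 53.2 on the treated arrays and 52.1 on the control array, and 10 lay below the middle of all genes on both. The luminal and epithelial list, 23 genes, had median percentiles of 61.4 and 55.6, and the mesenchymal list, 19 genes, of 42.7 and 46.7. Among single luminal genes, GATA3 was at 4.80 ± 0.10 (SD, n = 6) on the treated arrays and 7.71 on the control array, FOXA1 at 6.19 ± 0.45 and 8.96, XBP1 at 5.93 ± 0.47 and 9.43, and the cell adhesion gene CDH1 at 3.24 ± 0.13 and 6.48.

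Some genes of luminal and estrogen receptor identity lay near or below the background mean in cells labelled MCF-7, a line known for its estrogen receptor. TFF1, TFF3, PGR and AGR3 had means of 2.70, 2.21, 2.81 and 2.08 on the treated arrays, against a background mean of 2.93. On the control array they were at 3.61, 2.69, 2.94 and 2.49, against 3.78. They were chosen after their values were seen, while the fixed lists of estrogen receptor targets and luminal genes had medians at or above the middle of all genes. That middle is itself low, with medians of all probe sets of 3.41 to 3.48 on the treated arrays, so such a rank does not show expression. VIM lay at percentiles 99.4 (treated) and 99.5 (control) and CAV1 at 85.3 and 85.7. Below the middle lay 11 of 19 mesenchymal genes on both, and of 8 basal markers 4 (treated) and 6 (control). Arrays or RNA that failed on epithelial genes are argued against by KRT8, KRT18, KRT19 and EPCAM, whose lowest percentile on any array was 90.7. Cells of a line other than MCF-7 are a candidate explanation, as a hypothesis only, because CDKN2A, a gene deleted in MCF-7, lay at percentile 82.1 or higher on all 7 arrays. Cross-hybridisation of the CDKN2A probe sets stays open, and no genotype was measured. Drift within the line stays open for the luminal genes. It could not return a deleted gene, so it would need the CDKN2A signal to be false. Lowering by both treatments stays open too. The median percentile of 11 luminal genes differed by -2.43 points between the control and the treated arrays, but its members went both ways: 6 ranked higher on the control array, among them CDH1 (52.6 against 31.6), XBP1 (88.4 against 74.6), GATA3 (67.3 against 58.8) and FOXA1 (83.5 against 77.9), and 5 lower, among them ESR1 (31.5 against 52.5) and AGR2 (29.2 against 52.3).

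The comparison of the treatments allows 10 splits of the 6 treated arrays, too few for a share under 0.05. With limma, 0 genes passed the adjusted threshold in the real split and in all 10 splits. At an unadjusted p under 0.05 the real split had 330 genes and the highest other 715, and 7 of the 10 splits had as many as the real one. The 4 splits that put both arrays numbered 3 on the same side had 348, 490, 707 and 715 genes, and the highest of the splits that part them had 624. With those arrays as a batch term, 0 genes passed and 525 had an unadjusted p under 0.05. For the G2/M list the real median shift was 0.177 and the highest other 0.184, reached by 2 of the 10 splits counting the real one. For the histone list the values were 0.17 and 0.19, again with 2 splits. For the number of lists past the threshold they were 2 and 8, with 7 splits.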
